A study of Homo sapiens with 9 samples.

How the data were processed

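Total RNA from 9 cultures of primary human CD4 T cells was measured on 1-colour Affymetrix whole-transcript arrays after biotin labelling, 3 cultures each for a scrambled, a TERT-targeting and a TERC-targeting hairpin. Per the labels' protocols, CD4 T cells were purified from blood mononuclear cells and stimulated 24 hours after isolation with beads carrying antibodies to CD3 and CD28 in medium with 10 ng/ml IL-2. They were transduced 24 hours later in the presence of 8 µg/ml polybrene, and 2 µg/ml puromycin was added 24 hours after that. Cultures were split at day 6, split and stimulated again at day 12, and collected at day 15, per the labels' protocols. The deposited values are log2 signals per probe set, made by the authors with the robust multi-array average (RMA), per the submitters' processing notes. The version of RMA, its software, any filter and the genome build of the probe sets are not given in the sources used here, so no coordinates are reported. RMA summarises several probes into 1 value and equalises the distributions of the arrays, so a shift common to most genes could not be seen, and changes near the floor of the signal are compressed. The deposited values ran from 0.508 to 12.48, and all 9 columns matched 1 sample each by their labels.

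The table held 33297 probe sets. The platform annotation listed 21214 of them and did not list the other 12083. Of the listed probe sets, 19460 had 1 gene symbol and 1754 had several, and only those with 1 symbol were used for gene-level tests. Through their gene ID, 19429 of the 19460 matched the RefSeq gene table of assembly GRCh38.p14, which was used for names alone, and 0 symbols needed an update. Where a gene had more than 1 probe set (769 genes), the one with the highest mean over all arrays was kept, which left 18417 genes. Among named genes, the other probe set showed a much smaller change for LAYN (-1.19 and -0.10), TOX2 (-1.05 and -0.18) and CCR2 (0.74 and 0.29), and for RPL13, NHP2 and BIRC5 1 probe set did not pass in shTR against shScramble when all probe sets were tested together.

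Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). A single model with 3 group means was fitted to all 9 arrays, which gave 6 residual degrees of freedom per gene and 3.04 prior degrees of freedom. The contrasts were shTR against shScramble, shTERT against shScramble and shTR against shTERT. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 18417 genes. Means are given with the SD of 3 arrays, and intervals for the targeted genes are 95% confidence intervals from the model. The number of arrays limits the precision, and the median residual SD of a gene was 0.104 (log2).

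Gene groups came from 46 lists of pathways, T cell functions, markers of other cell types and markers of RNA quality. Of these, 45 had at least 5 measured genes and were tested with camera at a preset correlation between genes of 0.01, with adjusted p-values over the lists. Calls were repeated with the correlation estimated from the data and with the rotation test fry, whose directional p asks whether the genes of a list move one way on balance and does not compare them with other genes. Counts of members were also taken with p-values adjusted over the list alone. Named genes were TERC and TERT, the 10 largest rises and 10 largest falls per contrast among genes that passed and whose arrays did not overlap between the groups, and up to 4 passing members of each list with the largest changes, or 2 with the smallest p where none passed. Small RNAs, receptor and immunoglobulin segments, uncharacterised loci and sex-linked markers were not named among the largest changes. Groups, contrasts, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

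The overlap of the knockdowns was set beside 100 simulations of unchanged groups against shared control arrays and beside the overlap of independent lists. In the simulations all 9 arrays were drawn at random, each gene independently of the others. The alternatives were a filter on dim genes, median centring, a second quantile normalization, a trended and robust prior, a fit of 2 groups alone, the replicate number as a block, array weights, the mean of a gene's probe sets, all probe sets, and leaving out each array in turn. Splits of the arrays into other groups were counted, 10 for each pair of groups and 100 for all 9 arrays. On simulated data with 200 changed genes among 18417, a log2 change of 0.5 was recovered for 79.7% of genes in shTR against shScramble, 80.9% in shTERT against shScramble and 75% in shTR against shTERT, and a change of 1.5 for 100% in each. Data handling and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.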

Results

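Gene expression was profiled in primary human CD4 T cells that had been activated with beads carrying antibodies to CD3 and CD28 and transduced with a lentivirus encoding a short hairpin RNA. 3 hairpins were used, with 3 arrays each. The control hairpin had a scrambled sequence (shScramble), the second targeted TERT, the catalytic protein subunit of telomerase (shTERT), and the third targeted TERC, the RNA that serves as the template of telomerase and is called hTR in the labels (shTR). Cells were kept under puromycin and collected at day 15 of culture, after a second stimulation at day 12. The labels record apoptosis as normal in shScramble and shTERT cells and as increased in shTR cells. The design sets each knockdown against the scrambled control, and the knockdowns were also compared with each other, which tests whether their effects differed. The 9 arrays had medians between 3.95 and 4.02 (log2 signal), and across genes the arrays of a group correlated at 0.996 to 0.997, although genes are not independent replicates. The labels call the cultures biological replicates without saying whether they came from separate donors, so p-values measure the spread between these cultures. The number of arrays limits the precision of every value.

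The targeted transcripts were examined first. TERC (probe set 8092000) was lower in every shTR array than in any other array. The shTR arrays read 5.48, 5.97 and 5.56 (log2 signal), the shScramble arrays 7.30, 7.15 and 7.67, and the shTERT arrays 7.63, 7.47 and 7.63. The change between shTR and shScramble was -1.70 (95% confidence interval -2.06 to -1.35, n = 3 each, adjusted p = 0.000662), which left 30.7% of the control signal (24.1% to 39.3%). Against shTERT the change was -1.90 (adjusted p = 0.00124). TERC did not differ detectably between shTERT and shScramble, with a change of 0.20 (adjusted p = 0.664). For TERT (probe set 8110783) no difference was detectable on this array. The shTERT arrays read 4.41, 4.04 and 4.40, the shScramble arrays 4.47, 4.39 and 4.35, and the shTR arrays 4.39, 4.61 and 4.25. The TERT change between shTERT and shScramble was -0.12 (95% confidence interval -0.38 to 0.15, adjusted p = 0.747), and without shTERT replicate 2 it was 0.00. The interval spans 76.6% to 111% of the control signal. TERT lay between the 42.4th and 48.9th percentile of all genes in the 9 arrays, so its probe set does not check the shTERT label. The word knockdown therefore names shTERT by its hairpin alone, as lower TERT was not detected.

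**Figure D1:**
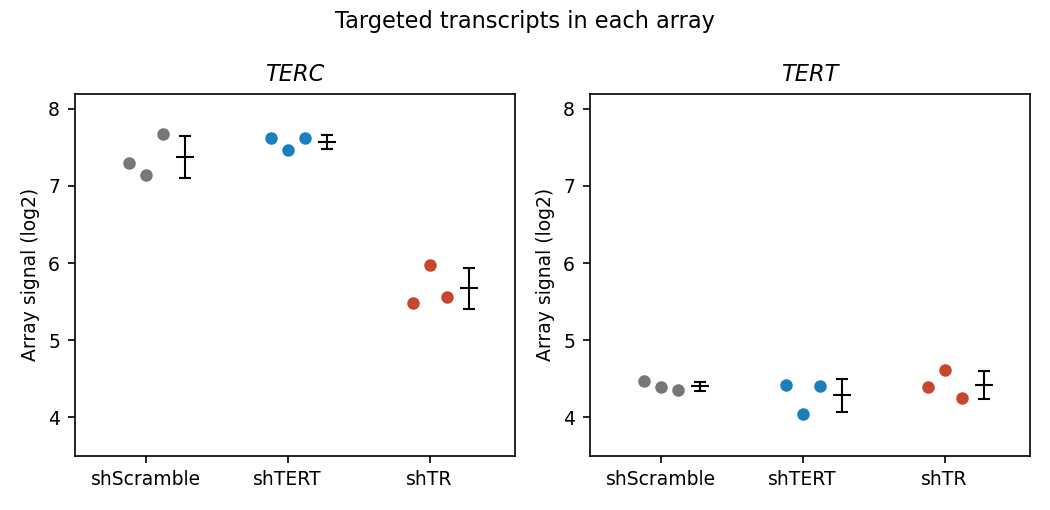
Array signal (log2) of TERC (left) and TERT (right), with 1 point per array and the mean ± SD of the 3 arrays of each hairpin beside the points. TERC lay between 5.48 and 5.97 in shTR and between 7.15 and 7.67 in the other groups, whereas TERT lay between 4.04 and 4.61 in all 3 groups with no detectable difference.

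In shTR cells, many interferon-stimulated genes were higher than in shScramble cells, and many genes of cholesterol synthesis and mitosis were lower. CXCL10, an interferon-induced chemokine that attracts activated T cells, rose 5.74-fold, from 6.69 ± 0.13 to 9.21 ± 0.29 (log2 signal, mean ± SD, n = 3 each, adjusted p = 0.000416). CXCL13, a chemokine that attracts B cells, rose 6.86-fold, from 4.37 ± 0.30 to 7.14 ± 0.37. INSIG1, an endoplasmic reticulum protein that restrains sterol synthesis and is itself a sterol-regulated gene, was 3.53-fold lower, at 5.95 ± 0.47 against 7.77 ± 0.01 (adjusted p = 0.00105). BCL2L11, which encodes the pro-apoptotic protein BIM, rose from 5.13 ± 0.10 to 5.97 ± 0.15 (adjusted p = 0.00231).

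Across 18417 genes, 1477 passed an adjusted p of 0.05 in shTR against shScramble, 639 higher and 838 lower. With each array centred on its median the split was 503 higher and 1147 lower. After a second quantile normalization it was 752 higher and 807 lower. Changes of at least 2-fold were found for 45 genes that rose and 29 that fell. The arrays of the groups did not overlap for 24.9% of all genes, against a chance share of 10%. The count was 815 without shScramble replicate 1, 730 without shScramble replicate 3, 910 without shTR replicate 1 and 949 with only these groups in the fit. Other large rises were those of CCR1, a receptor for inflammatory chemokines (log2 change 2.28), IGF1, insulin-like growth factor 1 (2.04), and CXCL11 (2.51), a ligand of the same receptor as CXCL10. In shScramble the signals of CCR1 (3.15) and CXCL11 (2.90) lay below the median gene. Other large falls were those of FADS1 (-1.46) and FADS2 (-1.38), desaturases of polyunsaturated fatty acids, NRIP3 (-1.51), BAIAP2L1 (-1.46) and TC2N (-1.33). Of the 20 genes with the largest changes, 19 passed again without each array in turn. The exception was CCL22, a chemokine that attracts CCR4-bearing T cells (-1.35, adjusted p = 0.0185), which did not pass without shScramble replicate 1 (adjusted p = 0.0719) or 3 (0.0626) or shTR replicate 1 (0.0609) or 3 (0.0567).

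**Figure D2:**
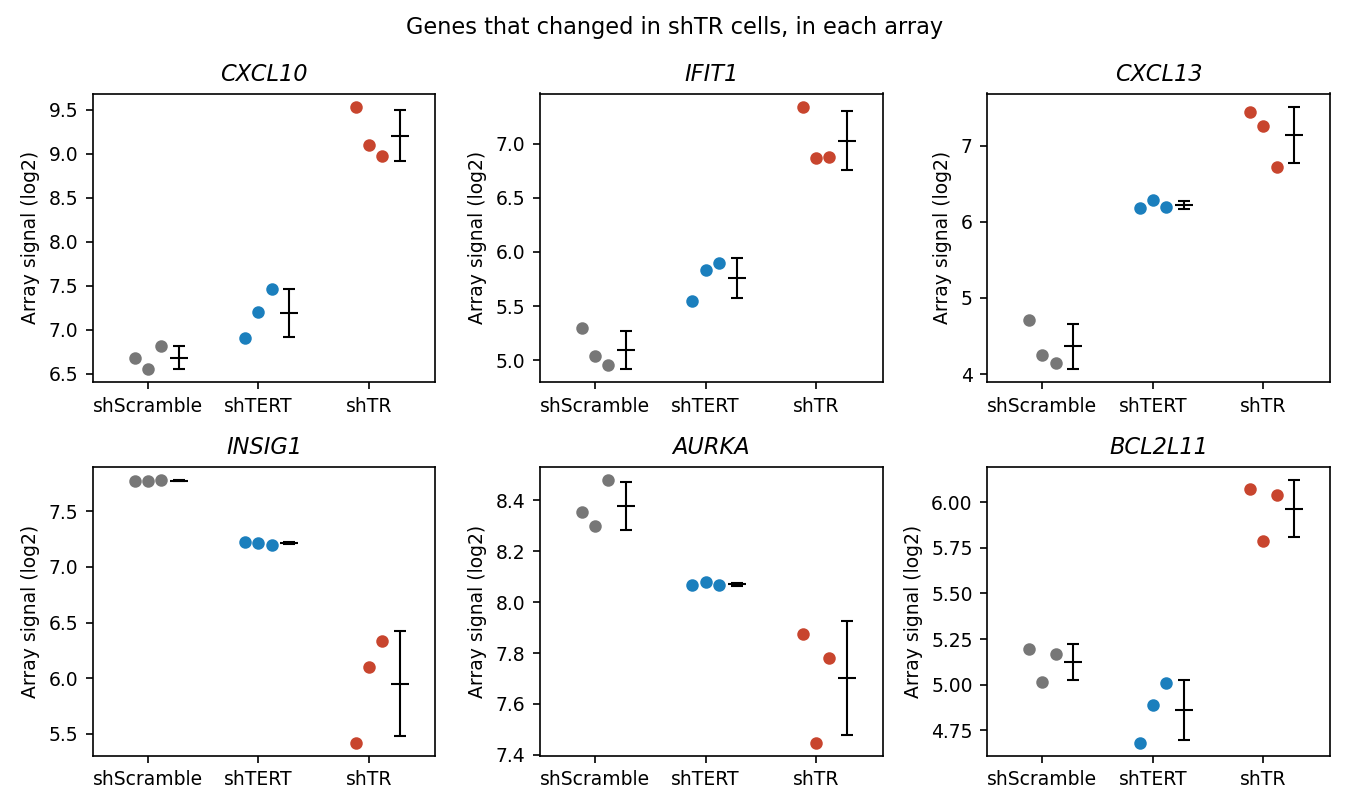
Array signal (log2) of 6 genes, with 1 point per array and the mean ± SD of the 3 arrays of each hairpin beside the points; each panel has its own signal range. CXCL10, IFIT1, CXCL13 and BCL2L11 were higher in every shTR array than in any shScramble array, and INSIG1 and AURKA were lower, with CXCL10 at 9.21 ± 0.29 in shTR and 6.69 ± 0.13 in shScramble.

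Of 27 interferon-stimulated genes, 20 rose in shTR cells and the other 7 did not pass. Adjusted over the list alone, 23 rose. IFIT1 and IFIT3, which encode interferon-induced RNA-binding proteins, rose by 1.93 and 1.78 (log2), IFI27 by 1.54 and RSAD2, which encodes the antiviral enzyme viperin, by 1.44. The median change of the list was 0.54, and the list passed the camera test (adjusted p = 1.25e-22, adjusted p = 0.184 with an estimated correlation). Of the 12 monocyte and macrophage markers 1 rose, S100A9 by 0.34 (adjusted p = 0.0278), which did not pass without shScramble replicate 1 (adjusted p = 0.0835), 2 (0.0827) or 3 (0.0687) or shTR replicate 2 (0.0817) or 3 (0.071). Of the 9 dendritic cell markers 1 fell, ITGAX (-0.88).

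Of 14 genes of cholesterol synthesis and its sterol control, 12 fell in shTR cells and the other 2 did not pass. By values adjusted over the list alone, 13 fell. Besides INSIG1, the largest falls were those of DHCR7 (-1.43) and CYP51A1 (-1.33), enzymes of the late sterol pathway, and HMGCS1 (-1.28), which makes HMG-CoA. The median change was -0.72 (camera, adjusted p = 8.94e-16, adjusted p = 0.144 with an estimated correlation).

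Of 21 genes of mitosis and the G2/M phase, 12 fell in shTR cells and the other 9 did not pass. Adjusted over the list alone, 19 fell. AURKA, which encodes a kinase of the spindle poles, fell by 0.68, TTK and BUB1, which encode spindle checkpoint kinases, by 0.52 and 0.51, and PTTG1, which encodes securin, by 0.44. The median change was -0.32 (camera, adjusted p = 1.93e-15, adjusted p = 0.175 with an estimated correlation). Of 21 genes of DNA replication and S phase, 1 fell, RRM1 (-0.19, adjusted p = 0.0464), and it did not pass without any of the 9 arrays (adjusted p between 0.0605 and 0.122). Their median change was -0.03, the list did not pass (camera, adjusted p = 0.209), and with quantile normalization the median was 0.01. Ribosomal protein genes moved little, with 5 of 25 lower and the other 20 not passed, 11 lower adjusted over the list alone and a median of -0.13 (camera, adjusted p = 5.53e-09, adjusted p = 0.144 with an estimated correlation). That count was 2 without shScramble replicate 1 or 2, 0 without shScramble replicate 3, 1 without shTR replicate 1 and 3 without shTR replicate 3. Of 19 genes of oxidative phosphorylation, 5 fell and the other 14 did not pass, with UQCRC1 of complex III at -0.35 and ATP5F1C of ATP synthase at -0.35. Adjusted over the list alone, 9 fell (camera, adjusted p = 2.68e-06, adjusted p = 0.144 with an estimated correlation). The count was 2 without shScramble replicate 3 or shTR replicate 1 and 3 without shTR replicate 2. The housekeeping genes, a list fixed to follow RNA quality, also passed (camera, adjusted p = 0.0057, adjusted p = 0.32 with an estimated correlation). Among its 11 genes 2 fell, PPIA (-0.45) and HPRT1 (-0.26), with 6 lower adjusted over the list alone. HPRT1 did not pass without shScramble replicate 1 (adjusted p = 0.0775), 2 (0.0522) or 3 (0.108) or shTR replicate 1 (0.06) or 2 (0.0711), and with genes of at least median signal the list did not pass (adjusted p = 0.0712).

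Single genes of the apoptotic machinery also changed in shTR cells, although 2 of the 4 apoptosis lists did not pass and most of their members did not. Of 11 pro-apoptotic BCL2 family genes, 3 rose and the other 8 did not pass, with 3 higher adjusted over the list alone. BCL2L11 rose by 0.84, BMF, a second gene for a BH3-only protein, by 0.59, and BBC3, which encodes PUMA, by 0.35. BBC3 did not pass without shScramble replicate 1 (adjusted p = 0.0647) or 3 (0.072) or shTR replicate 2 (0.0525). The median change of the list was 0.14 (camera, adjusted p = 0.00221, adjusted p = 0.144 with an estimated correlation). Of 13 death receptors and ligands, 2 rose, as they did adjusted over the list alone. They were FASLG (0.70), the ligand of the death receptor FAS, and TNFSF10 (0.66), which encodes TRAIL. That list passed narrowly (camera, adjusted p = 0.0454, adjusted p = 0.193 with an estimated correlation). It did not pass without shScramble replicate 2 (adjusted p = 0.0949), shTERT replicate 3 (0.0544) or shTR replicate 3 (0.18), with the replicate number as a block (0.0655) or with genes of at least median signal (0.0712). Of 11 caspase and apoptosome genes, the inflammatory caspases CASP1 (0.53) and CASP4 (0.49) rose and the initiator caspase CASP9 fell (-0.55), and of 8 pro-survival genes 1 fell, BIRC5, which encodes survivin (-0.38). Neither list passed (camera, adjusted p = 0.932 and 0.709). Without shScramble replicate 2, 2 caspase genes fell. With values adjusted over the list alone, 2 caspase genes rose, 2 fell and 1 pro-survival gene fell.

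Some cytokine genes rose in shTR cells. Of 16 effector cytokines, 8 rose and the other 8 did not pass. Among those that rose were IL6 (1.56), the T helper 2 cytokine IL4 (1.52) and the inhibitory cytokine IL10 (1.36). IL6 went from 2.73 to 4.29 and IL10 from 4.02 to 5.38 (log2 signal), both below the median gene in shScramble. Adjusted over the list alone, 9 rose and 1 fell, and with each array centred on its median 8 rose and 1 fell. The median was 0.47 (camera, adjusted p = 1.94e-06, adjusted p = 0.144 with an estimated correlation). Of 19 cytokine and chemokine receptors, 5 rose, including the IL-7 receptor IL7R (0.93), IL18RAP (0.84), the shared IL-6 family receptor IL6ST (0.62) and IL12RB2 (0.42). Adjusted over the list alone, 6 rose and 3 fell, with each array centred 5 rose and 2 fell, and without shTR replicate 2, 5 rose and 1 fell. This list passed narrowly (camera, adjusted p = 0.046, adjusted p = 0.193 with an estimated correlation), and not without shScramble replicate 2 (adjusted p = 0.0683) or 3 (0.0549), shTERT replicate 1 (0.0619) or shTR replicate 1 (0.0893) or 2 (0.0622). T cell activation markers and cytotoxic granule genes moved in both directions, and neither list passed (camera, adjusted p = 0.836 and 0.967). Of 13 activation markers 3 rose, among them the costimulatory receptor ICOS (0.66), and 2 fell, among them TNFRSF9 (-0.63, adjusted p = 0.0457), with 4 higher and 4 lower adjusted over the list alone. Those counts were 2 and 1 without shTERT replicate 1, 1 and 1 without shTR replicate 1 or 3, and 1 and 0 without any other single array. Of 11 cytotoxic granule genes, GZMA, which encodes granzyme A (1.21), and FASLG rose, and PRF1 (-0.40, adjusted p = 0.0324) and CST7 (-0.265, adjusted p = 0.0389) fell, with 2 higher and 3 lower adjusted over the list alone. The rises held without each array, and the falls numbered 1 without shScramble replicate 2, shTERT replicate 1 or shTR replicate 3 and 0 without any other single array. Among markers of other lymphocytes, the B cell marker CD22 was at -1.01 (adjusted p = 0.0301) and the NK cell marker KLRD1 at 0.43 (adjusted p = 0.0365). CD22 did not pass without shScramble replicate 1 (adjusted p = 0.106) or 3 (0.111) or shTR replicate 1 (0.101) or 2 (0.0756). KLRD1 did not pass without any single array other than shScramble replicate 1 (adjusted p between 0.0539 and 0.117). By limma 0 of 6 CD8 T cell markers passed, and 0 at an unadjusted p under 0.05.

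**Figure D3:**
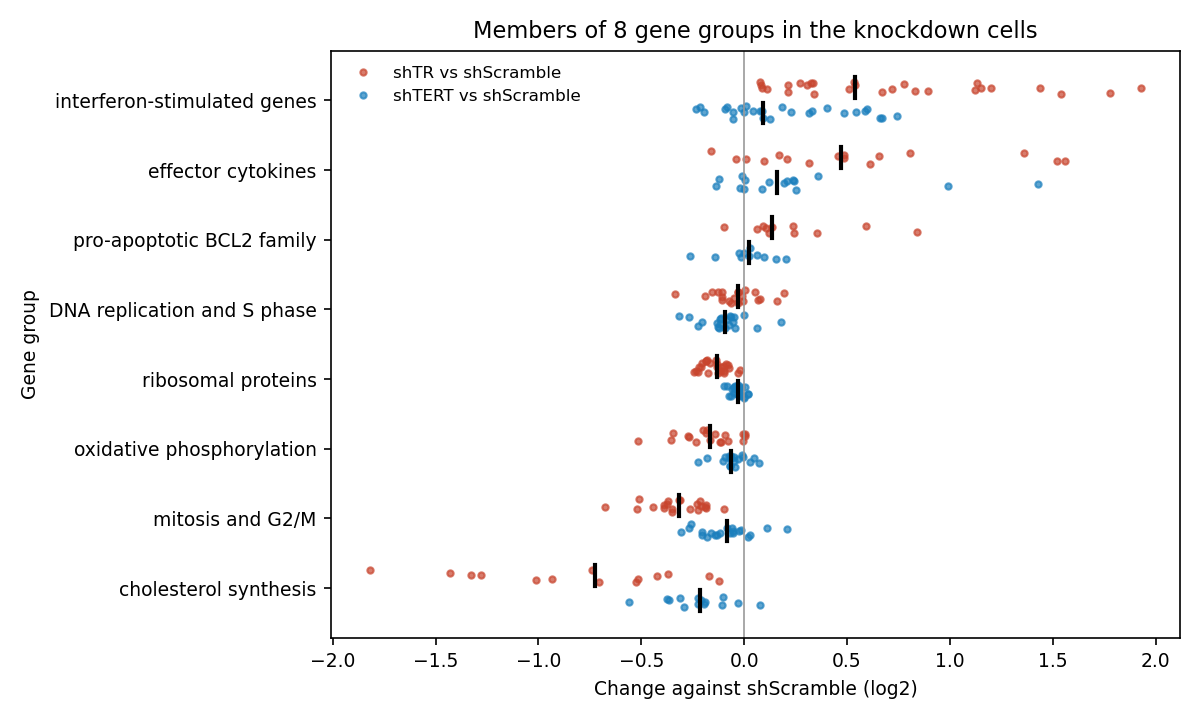
Log2 change against shScramble of the members of 8 gene groups in shTR cells (red) and shTERT cells (blue), with 1 point per gene and a black bar at the median of the group. In shTR the interferon-stimulated genes had a median of 0.54 and the cholesterol synthesis genes one of -0.72, and in shTERT these medians were 0.09 and -0.22.

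In shTR against shScramble, camera passed 14 of 45 lists, 7 higher and 7 lower, of which 0 passed with an estimated correlation (10 at an unadjusted p under 0.05). The rotation test fry, which does not compare a list with other genes, passed 17 lists.

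In shTERT cells, the largest changes against shScramble included rises of CXCL13 and IL2 and falls of EPAS1 and IL3RA. CXCL13 rose from 4.37 ± 0.30 to 6.22 ± 0.06 (log2 signal, mean ± SD, n = 3 each, adjusted p = 0.00379). IL2, which encodes the T cell growth factor interleukin 2, rose from 6.78 ± 0.14 to 8.21 ± 0.06, a 2.69-fold rise (adjusted p = 0.00038). IL7R rose by 1.12 and IL18RAP, a subunit of the IL-18 receptor, by 1.05. EPAS1, which encodes the hypoxia-inducible factor HIF-2 alpha, fell from 6.96 ± 0.18 to 5.45 ± 0.06 (adjusted p = 0.00038), and IL3RA, a subunit of the IL-3 receptor, fell by 1.43.

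In all, 243 genes passed in shTERT against shScramble, 134 higher and 109 lower, or 110 higher and 137 lower with each array centred on its median. After a second quantile normalization the split was 156 higher and 131 lower. Changes of at least 2-fold were found for 12 genes that rose and 6 that fell, and arrays did not overlap for 16.5% of all genes, against a chance share of 10%. The count fell to 71, 104 and 85 without shScramble replicates 1, 2 and 3 and to 138, 98 and 100 without shTERT replicates 1, 2 and 3. It was 438 with genes of at least median signal, 380 with a trended robust prior, 160 with only these groups in the fit, 135 with the replicate number as a block and 125 over all probe sets. Of the 20 genes with the largest changes, 11 passed again without each array in turn. They included the interferon-induced gene DDX60L (1.24), the histone gene H2BC12 (1.15), ENPP2, which encodes autotaxin (-1.19), the transcription factor gene TOX2 (-1.05, although a second TOX2 probe set was at -0.18) and the p53 target TP53INP1 (-0.91). SERPINA1 (1.36), the gene of alpha-1 antitrypsin, did not pass without shScramble replicate 1 (adjusted p = 0.0529) or 3 (0.0536).

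Of 27 interferon-stimulated genes, 4 rose in shTERT cells and the other 23 did not pass, with 9 higher and 2 lower adjusted over the list alone. IFI44L rose by 0.40, and the other passing members were IFI27 (0.74), MX2 (0.60) and CMPK2 (0.59). The count was 1 without shScramble replicate 1 or 3 or shTERT replicate 3, 2 without shScramble replicate 2 or shTERT replicate 2, and 8 without shTR replicate 1. The median change was 0.09 (camera, adjusted p = 0.000794, adjusted p = 0.693 with an estimated correlation), and the list did not pass fry (adjusted p = 0.16). Of 16 effector cytokines 1 rose, IL2, and adjusted over the list alone 2 rose (camera, adjusted p = 0.00928, adjusted p = 0.547 with an estimated correlation). This list did not pass without shTERT replicate 2 (adjusted p = 0.092) or by fry (0.0742). Of 19 cytokine and chemokine receptors, 3 rose and 1 fell, the IL-27 receptor IL27RA (-0.62), and adjusted over the list alone 4 rose and 2 fell (camera, adjusted p = 0.349). Without shTERT replicate 1, 2 rose and 2 fell. MYB, a transcription factor gene of less differentiated T cells, fell by 0.76, and PFKP, which encodes a glycolytic phosphofructokinase, rose by 0.46.

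Among apoptosis genes in shTERT cells, 1 of 13 death receptors and ligands rose, FASLG (0.69), 2 of 11 caspase and apoptosome genes rose, CASP1 (0.52) and CASP4 (0.49), and 1 of 8 pro-survival genes fell, BIRC5 (-0.61). None of these 3 lists passed (camera, adjusted p = 0.0601, 0.763 and 0.401). Adjusted over each list alone, 2 receptors and ligands rose, 3 caspase genes rose and 3 fell, and 1 pro-survival gene rose and 1 fell. CASP1 did not pass without shScramble replicate 1 (adjusted p = 0.0749), 2 (0.0749) or 3 (0.0973) or shTERT replicate 2 (0.0729) or 3 (0.0819), and without shTR replicate 2 a caspase gene also fell. Of the 11 pro-apoptotic BCL2 family genes, 0 passed by limma or adjusted over the list alone, 1 was higher and 1 lower at an unadjusted p under 0.05, and the list did not pass (camera, adjusted p = 0.793; fry, adjusted p = 0.599). BCL2L11 was at -0.27 (adjusted p = 0.34) and BMF at 0.20 (adjusted p = 0.404). For cholesterol synthesis, 0 of 14 genes passed by limma or adjusted over the list alone, although 8 were lower at an unadjusted p under 0.05. Their median was -0.22, and the list passed camera (adjusted p = 7.87e-05, adjusted p = 0.547 with an estimated correlation) and not fry (adjusted p = 0.125). For mitosis, 0 of 21 genes passed by limma, 1 was higher and 8 were lower at an unadjusted p under 0.05, and 2 fell adjusted over the list alone. The list passed camera (adjusted p = 0.000794, adjusted p = 0.574 with an estimated correlation) and not fry (adjusted p = 0.153). For S phase, 0 of 21 genes passed by limma or adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.000794, adjusted p = 0.547 with an estimated correlation; fry, adjusted p = 0.0742). Of 45 lists, camera passed 12, 4 higher and 8 lower. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), and fry passed 0 (17 at an unadjusted p under 0.05). The CD8 T cell marker GZMH was at 0.95 (adjusted p = 0.0559) and the dendritic cell marker CD1C at 0.63 (adjusted p = 0.0545).

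Some genes moved alike in both knockdowns. IL7R changed by 0.93 in shTR and 1.12 in shTERT, FASLG by 0.70 and 0.69, CASP4 by 0.49 and 0.49, and TP53INP1 was 2.01-fold lower in shTR and at -0.91 in shTERT. The direct tests of these differences did not pass (adjusted p = 0.476 for IL7R, 0.955 for FASLG, 0.984 for CASP4 and 0.739 for TP53INP1), which does not show that the changes were equal. CXCL13 rose in both and was higher in shTR than in shTERT (adjusted p = 0.035), and IL2 rose in both and was lower in shTR (adjusted p = 0.00453). In all, 164 genes passed in both comparisons with the same sign, 105 higher and 59 lower, which was 67.5% of the genes that passed in shTERT. Of these, 32 also differed between the knockdowns. Independent lists of these sizes would share 4.65 higher and 4.96 lower genes. Groups simulated as unchanged against shared control arrays shared a mean of 0.01 higher and 0 lower genes. Almost no gene passes in unchanged groups, so these counts were near 0 by construction and do not measure the excess. A further 4 genes passed with opposite signs, against 9.88 for independent lists. The simulations gave 0 such genes, for the same reason. The count of 164 was 49, 78 and 57 without shScramble replicates 1, 2 and 3, and 92, 63 and 69 without shTERT replicates 1, 2 and 3. It was 299 with genes of at least median signal and 94 with the replicate number as a block. Both comparisons used the same 3 control arrays, too few to split, so part of the excess may come from these shared controls. Across genes, which are not independent replicates, the log2 changes correlated at Pearson's r = 0.529, against 0.50 in the simulations. Their covariance was 0.0176 against 0.00498 simulated, a difference of 0.0126, which still includes any effect of the control hairpin itself. Genes were simulated as independent, so the difference may also include chance values of the control arrays that many genes share.

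**Figure D4:**
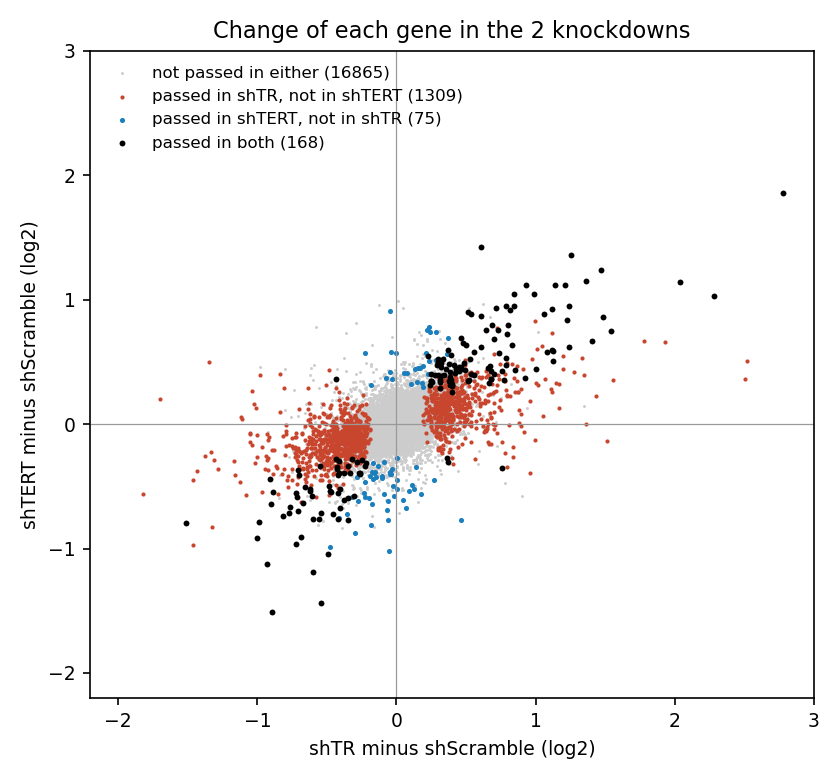
Log2 change of each of 18417 genes in shTR (horizontal axis) and shTERT (vertical axis) against shScramble, with 1 point per gene coloured by the comparisons in which it passed an adjusted p of 0.05. Of the genes, 1309 passed in shTR and not in shTERT, 75 in shTERT and not in shTR, and 168 in both, and the 3 control arrays are shared by both axes.

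In the direct comparison of the knockdowns, 15 of 27 interferon-stimulated genes were higher and 9 of 14 cholesterol synthesis genes lower in shTR than in shTERT cells, and single cytokine and chemokine genes differed in both directions. Both lists passed camera, but neither passed with an estimated correlation (adjusted p = 0.246 each). CXCL10 was 4.04-fold higher in shTR, at 9.21 ± 0.29 against 7.19 ± 0.28 (log2 signal, mean ± SD, n = 3 each, adjusted p = 0.0013). IL4 was 3.14-fold higher, at 6.96 ± 0.10 against 5.31 ± 0.16 (adjusted p = 0.00124). CCL22 was lower in shTR by a log2 change of -1.85, at 5.74 ± 0.62 against 7.59 ± 0.30 (adjusted p = 0.00995). BCL2L11 was 2.15-fold higher, at 5.97 ± 0.15 against 4.86 ± 0.16 (adjusted p = 0.00216).

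In all, 669 genes passed, 308 higher and 361 lower in shTR, with 19 and 19 of them changed at least 2-fold. The split was 259 higher and 381 lower with each array centred on its median, and 402 higher and 382 lower with a second quantile normalization. The arrays did not overlap for 18.9% of all genes, against a chance share of 10%. The count was 317, 288 and 393 without shTERT replicates 1, 2 and 3, and 299 and 437 without shTR replicates 1 and 2. It was 1219 with genes of at least median signal, 397 with the replicate number as a block and 173 with only these groups in the fit. Other large differences were IL10 (1.36), IL6 (1.20), CCR1 (1.25), the Fc receptor chain gene FCER1G (1.36) and SPP1, which encodes osteopontin (1.24). FCER1G passed in shTR against shScramble (0.96) and was at -0.40 in shTERT (adjusted p = 0.309). SPP1 was at 0.47 in shTR (adjusted p = 0.0648) and at -0.77 in shTERT (adjusted p = 0.0282). Among the lower genes were TMPRSS3 (-1.14), FADS2 (-1.12) and ZC3H6 (-1.10). Of the 20 genes with the largest differences, 16 passed again without each array in turn. CXCL11, with a 4.42-fold difference (adjusted p = 0.0214), was not among them and did not pass without shTERT replicate 1 (adjusted p = 0.0812) or 2 (0.0756) or shTR replicate 3 (0.052).

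Of 27 interferon-stimulated genes, 15 were higher in shTR than in shTERT and the other 12 did not pass, with 23 higher adjusted over the list alone. The differences were 1.27 for IFIT1, 1.21 for RSAD2 and 1.11 for IFIT3. The median difference was 0.46 (camera, adjusted p = 6.1e-23, adjusted p = 0.246 with an estimated correlation). Of 14 cholesterol synthesis genes, 9 were lower and the other 5 did not pass, with 12 lower adjusted over the list alone. INSIG1 was at -1.26, CYP51A1 at -1.11 and DHCR7 at -1.06, and the median was -0.57 (camera, adjusted p = 1.02e-12, adjusted p = 0.246 with an estimated correlation). Of 21 mitosis genes, 5 were lower and the other 16 did not pass, with 16 lower adjusted over the list alone and a median of -0.24 (camera, adjusted p = 6.61e-12, adjusted p = 0.246 with an estimated correlation). Without a single array that count of 5 was 1 (shScramble replicate 1 or 2), 3 (shScramble replicate 3) or 0 (any shTERT replicate, or shTR replicate 1 or 2). Of 11 pro-apoptotic BCL2 family genes, 2 were higher, BCL2L11 and PMAIP1 (0.38), and 4 adjusted over the list alone (camera, adjusted p = 0.00149, adjusted p = 0.212 with an estimated correlation). Without any of the 9 arrays 1 was higher. Of 13 death receptors and ligands 1 was higher, TNFSF10 (0.82), and that list did not pass (camera, adjusted p = 0.848). Of 16 effector cytokines 4 were higher and 1, IL2, was lower (-0.82), with 7 higher and 3 lower adjusted over the list alone. That list passed (camera, adjusted p = 0.0149, adjusted p = 0.403 with an estimated correlation), but not with genes of at least median signal (adjusted p = 0.348) or without shTR replicate 3 (0.0748).

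Of 45 lists, camera passed 15 between the knockdowns, 7 higher and 8 lower in shTR. With an estimated correlation 0 passed (7 at an unadjusted p under 0.05), and fry passed 14. A list fixed to follow RNA quality was among the 15, with the housekeeping genes PPIA (-0.42) and HPRT1 (-0.28) lower of 11 and 3 lower adjusted over the list alone (camera, adjusted p = 0.0207, adjusted p = 0.434 with an estimated correlation; fry, adjusted p = 0.0376). It did not pass with genes of at least median signal (adjusted p = 0.0985) or without shTR replicate 2 (0.124). The count of 2 was 0 without shTERT replicate 1 or 2 or shTR replicate 1 or 2, and 1 without any other single array. Of 18 glycolysis genes, 0 passed by limma, although 9 were lower at an unadjusted p under 0.05, 6 were lower adjusted over the list alone and the list passed camera (median -0.17, adjusted p = 1.07e-05, adjusted p = 0.461 with an estimated correlation) but not fry (adjusted p = 0.0795). Of 15 hypoxia genes, 1 was lower by limma and 4 were lower adjusted over the list alone, with a median of -0.40. That count of 1 was 0 in the lowest fit without 1 array. The list passed camera (adjusted p = 3.31e-05, adjusted p = 0.52 with an estimated correlation) but not fry (adjusted p = 0.173). Against shScramble its median was -0.18 in shTR and 0.19 in shTERT, and its estimated correlation between genes was 0.84. The monocyte marker S100A9 was higher by 0.36 (adjusted p = 0.0385) but did not pass without any of the 9 arrays (adjusted p between 0.0515 and 0.0972). The CD8 T cell and cytotoxic granule marker GZMH was at -1.08 (adjusted p = 0.0208) and did not pass without shTERT replicate 1 (adjusted p = 0.077), 2 (0.0514) or 3 (0.0695) or shTR replicate 2 (0.061). The dendritic cell marker ITGAX was at -0.67 (adjusted p = 0.0119) and did not pass without shTERT replicate 2 (adjusted p = 0.05).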

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

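The F test over the 3 groups and the tests on interferon-stimulated and mitosis genes were chosen after the result was seen, while the splits of single contrasts and the tests on genes moved alike were planned.

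For a single contrast, 6 arrays give 10 splits, too few for a share under 0.05. In each contrast 1 of the 10 splits, the real one, gave as many genes: 1477 for shTR against shScramble, 243 for shTERT against shScramble and 669 for shTR against shTERT, with 0 as the highest count of the other splits in each. By the F test over the 3 groups, 1336 genes passed in the real grouping and at most 329 in the others. Only 1 of 100 splits, the real one, gave as many, which is the smallest share that 100 splits can give. As the F test was chosen after the result was seen, chance is unlikely for that count but not excluded.

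Among probe sets outside the gene-level tests, differences between shTR and shScramble were also found when all probe sets were tested together. Of the 12083 probe sets that the annotation does not list, 154 passed, 57 higher and 97 lower in shTR, and of the 1754 with several gene symbols 59 passed, 35 higher and 24 lower. These probe sets are unnamed here.

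In 4 genes both knockdowns passed against the shared control with opposite signs, fewer than the 9.88 for independent lists. Each of 100 simulations of unchanged groups with shared control arrays gave 0, but almost no gene passes in such groups, so that count was fixed by construction. SECTM1, which encodes an interferon-inducible secreted and membrane protein, changed by 0.76 in shTR and by -0.35 in shTERT, a difference of 1.11. ITGAM, which encodes the integrin alpha M chain, changed by -0.44 and 0.36, a difference of -0.80 (-0.795). EIF4EBP2, which encodes a repressor of translation initiation, changed by 0.37 and -0.31, a difference of 0.68, and RNF213, which encodes an interferon-induced ubiquitin ligase, by 0.36 and -0.27, a difference of 0.64. The genes were picked by these signs, so a test of the difference adds no evidence. The change in shTR passed in 9 of 9 fits without 1 array for each gene, but the change in shTERT in 3 of 9 for ITGAM, EIF4EBP2 and RNF213 and in 0 of 9 for SECTM1. Fewer arrays cost power. With all arrays the shTERT and shScramble arrays of each gene did not overlap, but this held for all 243 genes that passed and adds no evidence.

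The first pattern weighed was the set of genes that moved alike in both knockdowns. The covariance across genes was 0.0176, above the highest of 100 simulations with chance values of shared control arrays (0.00529). The simulations drew each gene independently, whereas genes vary together. Their range may therefore be too narrow, and chance values of the control arrays are not excluded. If the control hairpin repressed transcripts of its own, genes higher in both knockdowns would prevail, and 64.0% of the 164 shared genes were higher in both (exact 95% interval 56.2% to 71.4%), between the bounds set beforehand. An effect of the control hairpin therefore cannot be told apart from an effect common to both knockdowns, because a single control hairpin was used. A shared consequence of targeting telomerase remains a hypothesis, as does a response to any targeting hairpin.

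The second pattern was the rise of interferon-stimulated genes in shTR cells. The cells had been purified as CD4 T cells, but more monocytes, macrophages or dendritic cells would raise their markers, and the median change of their 21 markers was -0.00134 (SE 0.0428, SD between markers 0.243), with 0 of them at the median of 0.54 of the interferon list. Of the 21, 4 lay above the median gene in control cells, and 2 belong to another list. Of those 4, CD68 went from 8.70 to 8.43, ITGAX from 7.61 to 6.73, AIF1 from 6.73 to 6.46 and TYROBP from 5.11 to 5.16. The only marker that passed higher was S100A9, from 2.63 to 2.97 (limma, adjusted p = 0.0278), and the floor-level LYZ went from 1.70 to 1.77. As most markers lay below the median gene, a small rise in these cells could go unseen. The median rests mostly on such dim markers, so more of these cells are not excluded. Genes outside the 2 lists were not weighed, among them FCER1G (0.96) and CCR1 (2.28), which rose, and ITGAM (-0.44), which fell. All 3 groups carried a hairpin vector, so a response to any vector could not by itself set shTR apart from shScramble. A response common to both targeting hairpins is argued against as the whole cause by the shTR minus shTERT median of 0.46 (SE 0.0848). Of the 27 genes, 15 were higher in shTR than in shTERT, but the list did not pass camera with an estimated correlation (adjusted p = 0.246). The SEs of these medians resample genes as if independent, so they do not measure the spread between cultures. A single shTR array is argued against by the 17 of 20 genes that still rose in the lowest such count. A response to the shTR hairpin sequence or to its dose, as distinct from the loss of TERC, may account for the rise and stays open, since 1 hairpin per target confounds it with the group.

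The third pattern was the fall of mitosis genes in shTR cells. Fewer cells in cycle at any stage would lower S phase genes by about as much. This assumes that both lists follow cycling cells alike, which was not tested. On that assumption, fewer cells in cycle are argued against as the whole cause. The median of the DNA replication and S phase list lay 0.29 (SE 0.0539) above that of the mitosis genes. This SE too comes from resampling genes rather than cultures. The list of replication-dependent histones, also S phase genes, was lower, with 3 of 15 lower, 0 higher and a median of -0.13 (camera, adjusted p = 0.0149, adjusted p = 0.193 with an estimated correlation). The histone gene H2BC12, outside that list, rose by 1.36 (limma, adjusted p = 0.000662). A smaller share of cells in cycle could therefore contribute and stays open. A single shTR array is argued against by the 9 of 12 genes that still fell in the lowest count without 1 of these arrays. A change in the share of cells in G2 and mitosis remains a hypothesis, because cell cycle stages were not measured here and an effect of the hairpin sequence is confounded with the group.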

How the results depend on the processing

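The F test, the counts of list members without each array and the overlap without each shTR or shTERT array were chosen after the data were seen. No gene that passed reversed in any alternative that tested it, and no list call reversed. For shTR against shScramble the 1477 genes became 949 with only the 2 groups in the fit, which has fewer residual degrees of freedom, and 730 to 1385 without 1 array, and the other alternatives gave 1123 to 2056. The 243 genes of shTERT against shScramble became 438 with genes of at least median signal, 380 with a trended robust prior, 160 with only the 2 groups, 125 over all probe sets, where more values are tested, and 71 to 229 without 1 array. The 669 genes between the knockdowns became 1219 with genes of at least median signal, where fewer genes are tested, 173 with only the 2 groups and 288 to 586 without 1 array. The overlap of 164 became 299 with genes of at least median signal and 49 to 142 without 1 array. With the replicate number as a block the counts were 1123, 135 and 397 and the overlap 94. The same-number deviations correlated at -0.132 to 0.144 (median -0.00551) and 2 of 9 arrays lay closest to their own number, so the numbers do not pair the arrays. Lists passing camera went from 14, 12 and 15 to 13, 13 and 14 with that block and to 0, 0 and 0 with an estimated correlation (10, 3 and 7 at unadjusted p under 0.05), and fry passed 17, 0 and 14 (17 unadjusted for shTERT, lowest adjusted p = 0.0742). The TERT change in shTERT was -0.18 to 0.00 without 1 array and turned to 0.00397 without shTERT replicate 2. For the target gene TERT, shTR vs shScramble gave a change of 0.01, which turned to -0.0254 with centred arrays, -0.0192 with quantile normalization, -0.0198 with array weights, -0.01 without shScramble replicate 3 and -0.0824 without shTR replicate 2 (highest 0.0951). None of these TERT values passed. Except where a construction is named, the cause was not tested. The TERT probe set lay below the median signal of the genes, so a change of that transcript could go undetected (-0.18 at the lowest).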

Other observations

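Counts of list members without each array were added after the data were seen. Genes induced early after T cell receptor signalling moved in both directions in shTR cells. Of 16 immediate early and AP-1 genes, 3 rose and 7 fell against shScramble, with NR4A1, an orphan nuclear receptor gene induced by antigen receptor signalling, at -1.05, the transcription factor gene EGR3 at -0.71 and FOSB at 0.97. Adjusted over the list alone, 5 rose and 7 fell, and the list did not pass (camera, adjusted p = 0.227). The counts were 2 and 4 without shScramble replicate 1, 1 and 5 without shScramble replicate 2, 1 and 4 without shScramble replicate 3, 1 and 5 without shTR replicate 1 and 3 and 4 without shTR replicate 2. Between the knockdowns 5 were lower in shTR and 0 higher, with NR4A1 at -0.98, NR4A3 at -0.92 and NR4A2 at -0.92, and the list passed (camera, adjusted p = 0.00508, adjusted p = 0.403 with an estimated correlation). By values adjusted over the list alone 2 were higher and 7 lower in that comparison, and without shScramble replicate 2 the counts were 1 higher and 4 lower.

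The lists of telomerase partners, telomere maintenance, p53 targets and DNA damage did not pass in shTR cells, which does not show that they were unchanged. The counts for telomerase and its partners do not include TERC, which fell as given above. Of these 15 genes 2 fell, RUVBL2 (-0.32, adjusted p = 0.029) and NHP2 (-0.30, adjusted p = 0.0244), as they did adjusted over the list alone (camera, adjusted p = 0.209). That count was 1 without shScramble replicate 1 or shTR replicate 3 and 0 without shScramble replicate 2 or 3 or shTR replicate 1 or 2. Of 13 shelterin and telomere maintenance genes 1 fell, STN1, which encodes a subunit of the CST complex at telomere ends, from 7.28 ± 0.14 to 6.49 ± 0.08 (log2 signal, mean ± SD, n = 3 each, adjusted p = 0.00344). STN1 was also lower in shTR than in shTERT (-0.79, adjusted p = 0.00797), and adjusted over the list alone it was again the 1 gene that fell against shScramble (camera for the list, adjusted p = 0.489). Of 24 p53 target genes 2 rose and 3 fell, with TP53INP1 2.01-fold lower and the cyclin gene CCNG1 at -0.86 (camera, adjusted p = 0.799), and adjusted over the list alone 3 rose and 3 fell. The counts were 1 and 2 without shScramble replicate 1 or 3 or shTR replicate 1 or 2. Of 17 DNA damage genes 4 rose and 2 fell, with the checkpoint kinase genes CHEK2 at -0.62 and ATM at 0.43, and TP53BP1 at 0.31 (camera, adjusted p = 0.856), and adjusted over the list alone 5 rose and 4 fell. The counts were 3 and 1 without shScramble replicate 1 or shTR replicate 2, 2 and 1 without shScramble replicate 3 or shTR replicate 1, and 2 and 2 without shTR replicate 3.

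Of 15 replication-dependent histone genes 3 fell in shTR cells, among them the linker histones H1-1 (-0.72) and H1-5 (-0.40), and 4 fell adjusted over the list alone. The list passed (camera, adjusted p = 0.0149, adjusted p = 0.193 with an estimated correlation) but did not with genes of at least median signal (adjusted p = 0.14). Of the lysosomal membrane genes, LAMP1 rose by 0.63 in shTR, and LAMP2 was at -0.34 in shTR and -0.77 in shTERT, with the knockdowns differing by 0.43 (adjusted p = 0.00574). The heme oxygenase gene HMOX1 rose by 0.64 in shTR and was 0.70 above shTERT, and NOLC1, which encodes a nucleolar protein that binds small nucleolar RNA-protein complexes, was at -0.48 against shScramble and -0.61 against shTERT.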
